A study of Homo sapiens with 131 samples.

How the data were processed

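The series holds 131 samples in 68 groups of human HCT116 and HEK293T cells, and each sample was placed in its group by its title or description. Per the labels' protocols, RNA was extracted with TRIzol, short-read libraries were made with an mRNA kit from total RNA, and long reads came from a nanopore cDNA kit. The submitters' processing notes name genome build hg38, FastQC 0.11.9, cutadapt 1.18, STAR 2.7.9a and featureCounts 2.0.1, with no order or role. The caller and filters of edited sites, the way TPM was computed, the replicate combination behind translation efficiency and the tail caller are not given in the sources used here.

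For each gene and editing library the authors deposited read counts, edited-read counts and the edited fraction, and the fraction equals edited reads over reads wherever a gene had reads. For uninduced cells the deposited values are TPM, normalized by the authors. For polysome data the deposited values are log2 translation efficiency, 1 value per genotype and line although the labels list 2 libraries per genotype and fraction, so that replicates had been combined by the authors. For nanopore libraries the deposited tables hold per gene the tail length and the counts of reads for reads edited by both editors and for the others. Gene positions came from a table of assembly GRCh38.p14.

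Edited reads were tested with edgeR 4.0.16 (quasi-likelihood test in R 4.3.3), with the log of the gene's reads as offset, over genes with at least 20 reads in every library and 10 edited reads over the libraries of the comparison. Each fusion was compared with the editor-only control of its own line, the dual editor with the pair of unfused editors, and each rapamycin time with 0 min of the same construct. P-values were two-sided and adjusted by Benjamini and Hochberg with a threshold of 0.05. The design fixed before the data were examined named limma on log2 scores for these files. Counts were found, so edgeR became the main test, and limma 3.58.1 and DESeq2 1.42.0 were kept as alternatives. Editing relative to library-wide editing used the same fit with the library-wide edited share in the offset, and was added after the data were seen. Uninduced TPM were tested with limma's trend method on log2(TPM + 1) for genes with a mean TPM of at least 1. Gene lists were tested with camera at a preset correlation of 0.01, with an estimated correlation and fry as alternatives. Scores, translation efficiency and tails of a list were also ranked against 10000 random lists of the same size matched on expression, and such percentiles describe these libraries only. Translation efficiency and tails had no replicates and got no test. Shares of single libraries and of genes have exact Clopper-Pearson 95% intervals. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 was used for the rest.

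The 24 lists, fixed before the data were examined, were P-body and decapping factors, CCR4-NOT and miRNA silencing factors, targets of let-7 and miR-17, chromatin factors, mitotic factors, immediate early and AU-rich mRNAs, interferon-stimulated genes, unfolded protein response and ATF4 targets, p53 targets, cholesterol synthesis, glycolysis, proteasome, translation factors, tubulin and actin genes, nuclear RNAs, selenoprotein genes, HCT116 markers, HEK293T markers, cytosolic and mitochondrial ribosomal protein genes, mitochondrially encoded mRNAs, oxidative phosphorylation genes, replication-dependent histones, and zinc finger genes. Genes were named by a rule with several parts. DDX6 and the P-body factors were named everywhere. Each tested comparison named the 8 largest rises and 8 largest falls that passed, with a level of at least 5 and no overlap between replicates. Each described list named its 2 largest members per direction at that level. Each editing file named its 8 protein-coding genes of highest score at that level. Tails named the 4 longest and 4 shortest differences with at least 20 reads per class. The text prints part of the genes so chosen.

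Editing libraries held 6259071 to 13432692 reads. Of 41 pairs of replicate libraries, 15 differed in reads by no more than counting noise. These 15 included both groups of the HCT116 dual-editor comparison and DDX6-STAMP-ID at 0, 15 and 120 min, whose replicates may be technical. Edited reads of the pairs differed by more than counting noise, with a chi-square per degree of freedom of 1.11 to 1.88. The libraries were therefore kept apart, although this does not show separate cultures. APOBEC1-DDX6 libraries 2 and 3 did not differ in reads by significantly more than counting noise (chi-square per degree of freedom 1.02, p = 0.0645), while the other pairs of that group did. Counting them as 1 sample gave 4181 genes higher instead of 4330. Same-numbered LSM14A-TRIBE-ID libraries deviated together across times, with correlations of 0.712 to 0.833 over 20 pairs, so their numbers, taken from the labels, pair them. The main fit did not use this pairing, and a replicate block was run as an alternative. The fit was checked on simulated counts drawn from the real means. For APOBEC1-DDX6 (7878 genes) 3.26% of genes changed 1.5-fold and 41.9% of those changed 3-fold were recovered, for the HCT116 dual editor C-to-U (6545 genes) 0% and 29.7%, for DDX6-STAMP-ID at 120 min (5648 genes) 0% and 10%, and for uninduced TPM (16080 genes) 25% and 73.2%. False calls numbered 0, 0, 0 and 6. Few genes were changed in the simulations, such as 92 by 1.5-fold and 93 by 3-fold for APOBEC1-DDX6, where the real comparison called 4330 higher. The adjustment over genes passes more of them where more change, so the simulated recovery can understate that of such a comparison. For uninduced TPM the simulated spread was taken over both groups, so that real differences between them counted as spread. Its recovery therefore does not describe the power of the real comparison.

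Alternatives were other tools, pseudocounts, filters, scalings, a replicate block and leaving out each replicate. The 20 samples with rapamycin and thapsigargin were not analysed here. No level of total RNA from the knockout cells was used here, so the knockout was not checked by level and no abundance change is given. No site positions were used here, so editing is given per gene.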

Results

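Processing bodies (P-bodies) are cytoplasmic granules of mRNA and of proteins that repress translation, remove the cap or shorten the poly(A) tail. The series fused proteins of these granules to an RNA deaminase, so that RNAs near the fusion carry edited bases. APOBEC1 converts C to U (the STAMP assay) and ADAR2dd, the deaminase domain of ADAR2, converts A to I (the HyperTRIBE assay). The fusions were expressed in HCT116, a colorectal carcinoma line, or in HEK293T, an embryonic kidney line. The editing measurements covered 83 libraries of 6259071 to 13432692 reads, with a median of 9976552, and gave for each gene the reads and the edited reads. Most fusions had 2 libraries, APOBEC1-DDX6 and its APOBEC1 control had 3, and a few had 1. Further data were RNA levels of uninduced HCT116 lines, translation efficiency of wild-type and DDX6-knockout cells in both lines, and poly(A) tail lengths from nanopore reads. The labels do not say that replicates came from separate cultures, so every p-value measures only the spread between these samples, which may be technical. Intervals and floors cover counting error only. A score is the percent of a gene's reads that were edited. A fold against a control without any edited read is a lower bound, set by the 3 counts that a count of 0 allows over the control group. All positions are on GRCh38. Scores of ribosomal protein genes, GAPDH, HSPA8, elongation factors and ALPP/ALPG are uncertain where reads could be shared with near-identical copies, as are those of overlapping genes such as PMF1.

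The first question was how strongly each fusion marked RNA. LSM14A-ADAR2dd, a fusion of the P-body scaffold protein LSM14A, edited 4.93% ± 0.0436 (SD, n = 2) of reads against 0.232% in the ADAR2dd control (n = 2), 21.2 times as much. 4E-T-ADAR2dd, built on the eIF4E-binding protein encoded by EIF4ENIF1, edited 2.41% ± 0.0115 and PATL1-ADAR2dd 1.09% ± 0.0117. DDX6-ADAR2dd reached 0.906% and ADAR2dd-DDX6 0.802%, both carrying the RNA helicase DDX6. The remaining ADAR2dd fusions lay lower, at 0.514% for ADAR2dd-LSM14A, 0.430% for ADAR2dd-EDC3, 0.355% for ADAR2dd-4E-T, 0.324% for EDC3-ADAR2dd and 0.306% for ADAR2dd-PATL1. Among APOBEC1 fusions APOBEC1-DDX6 was highest at 1.32% ± 0.0474 (n = 3), against 0.313% ± 0.00323 (n = 3) in the APOBEC1 control. LSM14A-APOBEC1 reached 0.680%, APOBEC1-PATL1 0.675% and 4E-T-APOBEC1 0.576%. DCP2-APOBEC1, a fusion of the decapping enzyme, lay below its control at 0.186% ± 0.0199 (n = 2), as did EDC4-APOBEC1 at 0.293% ± 0.0189 (n = 2). Single libraries, which allow no test, gave 0.603% for APOBEC-EDC3 (exact Clopper-Pearson 95% interval 0.597 to 0.609), 0.493% for APOBEC-DCP2 (0.488 to 0.499) and 0.488% for APOBEC1-EDC4 (0.483 to 0.494). Also below the control, in 1 library each, were fusions of the deadenylase subunit CNOT10 at 0.229% (0.227 to 0.232) and 0.208% (0.206 to 0.211), CNOT1-R-APOBEC1 at 0.225% (0.222 to 0.228) and APOBEC1-LSM14A at 0.305% (0.301 to 0.309). The control share was taken over 11914 genes, that of APOBEC1-LSM14A over 10723 and those of the CNOT fusions over 11152. The small gap of APOBEC1-LSM14A could come from the genes counted. The values of CNOT10-APOBEC1 (0.208%) and CNOT1-R-APOBEC1 follow the sample titles, which the column names match, while the file list attaches each file to the other sample.

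Reads of the tagged gene were compared first, since the transgene adds to them. EIF4ENIF1 had 484 RPM (reads scaled by library size) in 4E-T-ADAR2dd cells against 36.5 in the control, LSM14A had 320 RPM against 179 in LSM14A-ADAR2dd cells, and DDX6 had 468 RPM against 364 in APOBEC1-DDX6 cells. In HEK293T cells carrying both editors DDX6 stood at 1739 RPM against 217 and LSM14A at 954 against 204. The difference was small for DDX6-APOBEC1 (1.03-fold), DCP2-APOBEC1 (1.07-fold) and APOBEC1-LSM14A (1.14-fold). Editing scores of DDX6, LSM14A and EIF4ENIF1 can include transgene reads in cells that carry a fusion of that protein.

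**Figure D1:**
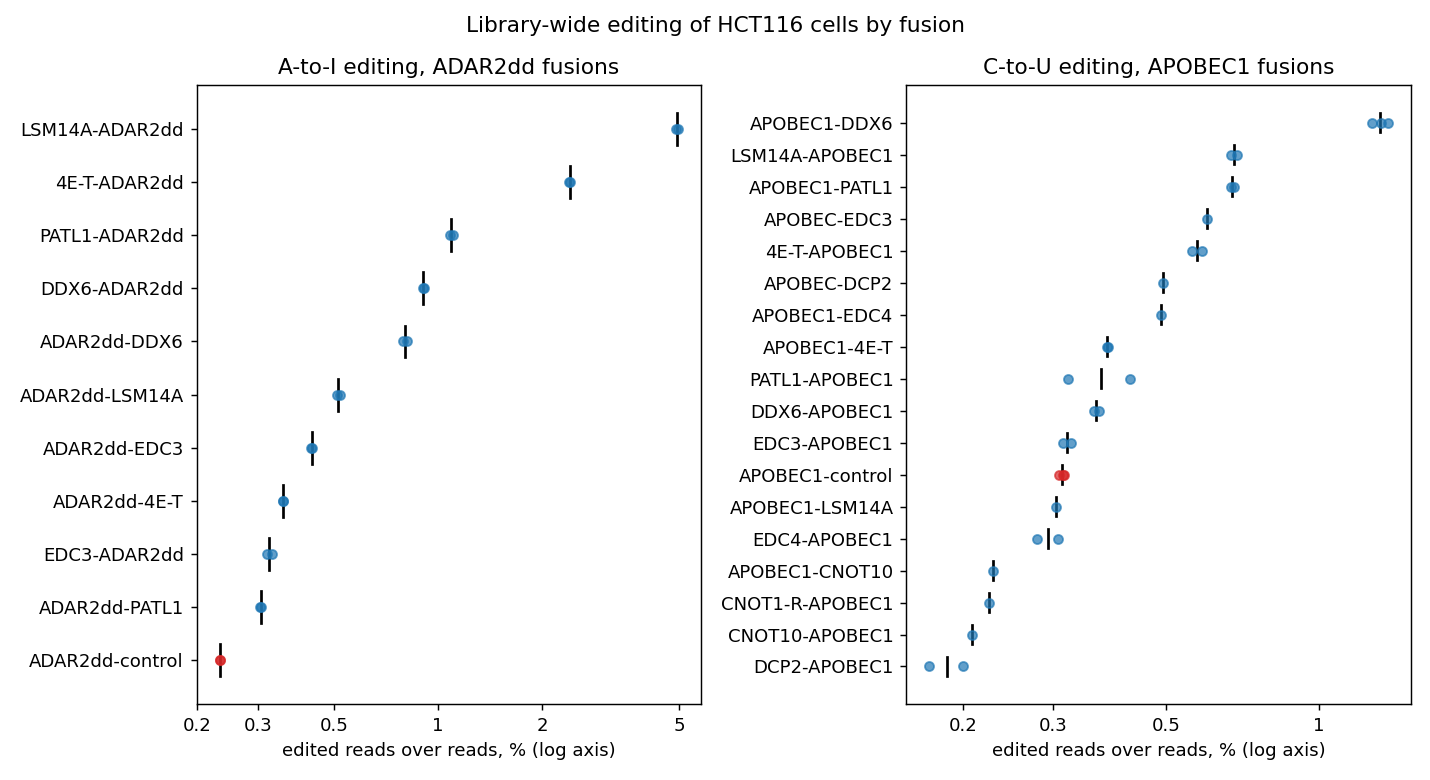
Edited reads as percent of all reads (log axis) for each fusion in HCT116 cells, A-to-I in one panel and C-to-U in the other. Points are libraries, black bars are means and red points are the editor-only control; LSM14A-ADAR2dd lies at 4.93% and APOBEC1-DDX6 at 1.32%.

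The next question was which mRNAs LSM14A-ADAR2dd marked. The sterol isomerase gene EBP (chromosome X, 48521808 to 48528716) was edited in 33.6% ± 0.589 of its reads (n = 2) and had no edited read in the control, at least 75.8-fold higher. RPS27 (chromosome 1, 153990762 to 153992155) reached 26.3% ± 0.00287, at least 303-fold higher, and MORN2 33.4% ± 1.09, at least 18.8-fold higher. NDUFB2 of respiratory complex I (chromosome 7, 140696708 to 140706643) rose from 0.947% ± 0.129 to 30.9% ± 0.273, the ferritin light chain gene FTL (chromosome 19, 48965309 to 48966879) from 3.18% ± 0.309 to 27.5% ± 0.563, and VPS4A from 1.97% ± 0.439 to 25.7% ± 1.83. PMF1 (chromosome 1, 156213007 to 156240042) had the highest score, 37.6% ± 3.74, and also a high control score of 17.9% ± 1.49 (adjusted p = 0.00621). The largest bounds belonged to abundant mRNAs: EEF2, a translation elongation factor, at 8.40% ± 0.162 (at least 1245-fold higher), GAPDH at 9.93% ± 0.448 (at least 1182-fold), the chaperone gene HSPA8 at 10.6% ± 0.151 (at least 936-fold) and FASN, the fatty acid synthase gene, at 5.25% ± 0.129 (at least 553-fold). By edgeR's quasi-likelihood test 7810 of 8392 genes rose and 3 fell. Relative to library-wide editing the split was 1059 higher and 907 lower. BUD13 fell from 2.21% ± 0.482 to 0.228% ± 0.323 (adjusted p = 0.0360) and GINS1 from 8.75% ± 0.0177 to 2.72% ± 3.85 (adjusted p = 0.0423), the latter with a spread in the fusion above its own mean. The last of the 3, chosen after its values were seen, was the phospholipase gene GPLD1.

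mRNAs of P-body proteins were themselves edited. DDX6 (chromosome 11, 118747763 to 118791744) rose 22.8-fold to 12.3% ± 0.540, the decapping enzyme gene DCP2 31.7-fold to 14.6% ± 0.580, EIF4ENIF1 (chromosome 22, 31436963 to 31493568) 13.5-fold to 12.1% ± 2.99, the exonuclease gene XRN1 15.8-fold to 8.20% ± 0.817, and EDC3 (chromosome 15, 74630558 to 74696024) 22.6-fold to 8.22% ± 1.66. LSM4 scored 11.8% ± 0.778 against 0.0471%, and PATL1 (chromosome 11, 59636716 to 59669037) scored 9.20% ± 2.13 against 0.129%. LSM5 scored 2.30% ± 1.77 against 0.943% and did not pass (adjusted p = 0.218). Of 18 P-body and decapping factors 17 rose, and 3 stood above library-wide editing over all genes tested, also 3 adjusted over the list alone. Their median score was 6.91%, against 4.42% for random lists of like expression (percentile 99.8 of 10000 lists). The list test against other genes gave adjusted p = 0.0310, and adjusted p = 0.549 with an estimated correlation.

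Cytosolic ribosomal protein mRNAs were marked by LSM14A-ADAR2dd above lists of like expression. All 71 rose, with a median score of 8.01% against 4.10% for lists of like expression. Relative to library-wide editing 56 were higher and 2 lower, and 60 and 3 adjusted over the list alone (list test adjusted p = 2.1e-18). RPL14 rose 8.16-fold to 4.45%, and RPL23 scored 0.987% ± 1.40 against 0.299%. Of 34 translation factors 20 stood above library-wide editing and 0 below, with 21 and 0 adjusted over the list alone (adjusted p = 2.8e-07), among them EIF4G2 at 5.13% (at least 359-fold higher). In the tubulin and actin list 12 were higher and 1 lower, the same counts adjusted over the list alone (adjusted p = 0.00532). ACTB reached 3.52% and CFL1, which severs actin filaments, 5.04%. Cholesterol synthesis genes gave 9 higher and 0 lower, 10 and 0 adjusted over the list alone (adjusted p = 0.00836), with HMGCS1 at 4.70% and no edited read in the control. Zinc finger genes went the other way: 130 of 169 rose, but 3 were higher and 41 lower relative to library-wide editing, 4 and 47 adjusted over the list alone (adjusted p = 2.8e-07). ZNF664 reached 6.73%, while ZNF264 scored 2.99% against 3.38% (adjusted p = 0.556). Immediate early and AU-rich mRNAs had a low median score of 1.97% (percentile 0 among like lists), with ZFP36L1, an AU-rich element binding protein, at 0.720% against 0.230% (adjusted p = 0.0993). Of this list 1 was higher and 1 lower, 0 and 0 adjusted over the list alone, and it was not called (adjusted p = 0.0538). Chromatin factors had a positive list call (adjusted p = 0.00857) although their median fold lay below that of all genes, with 8 higher and 7 lower, 9 and 10 adjusted over the list alone. Each of these list calls was lost with an estimated correlation (adjusted p = 0.549 with an estimated correlation, or above).

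The same question was asked of APOBEC1-DDX6. SPTSSA, a subunit of serine palmitoyltransferase (chromosome 14, 34432788 to 34462240), rose 7.82-fold from 2.49% ± 0.503 to 19.3% ± 1.49 (n = 3 and 3), and ARL6IP1 (chromosome 16, 18791667 to 18801549) 17.1-fold from 0.960% ± 0.261 to 16.3% ± 0.857. SH3BGRL reached 15.1% ± 1.03, the lysosomal peptidase gene TPP1 12.8% ± 1.23, SELENOF 12.4% ± 0.981 and B2M, the light chain of MHC class I, 12.3% ± 0.111 from 3.51% ± 0.245. The largest bounds were CCND1, which encodes cyclin D1 (chromosome 11, 69641156 to 69654474), at 3.01% ± 0.0490 and at least 205-fold higher, and the EGF-family ligand gene EREG at 4.16% ± 1.10 and at least 170-fold higher. PTGES3 followed at 3.61% ± 0.212 (at least 153-fold higher). By edgeR 4330 of 8325 genes rose and 227 fell, and relative to library-wide editing 918 were higher and 1689 lower. ECI2 fell from 7.65% ± 0.473 to 0.0835% ± 0.0734, FRG1 from 8.73% ± 2.96 to 0.0779% ± 0.135, and EIF4EBP1, a translation repressor, from 10.6% ± 1.04 to 0.148% ± 0.257. RPS15 had no edited read in the fusion against 0.634% ± 0.0693, at least 17.9-fold lower.

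Of 21 P-body factors 9 rose under APOBEC1-DDX6. DDX6 scored 1.36% ± 0.231 against 0.0369% (36.2-fold), LSM14A (chromosome 19, 34172504 to 34229288) 1.62% ± 0.498 against 0.199% (7.95-fold), PATL1 2.27% ± 0.208 (7.64-fold), XRN1 2.94% (3.45-fold) and DCP2 2.77% ± 0.598 (3.06-fold). EDC3 scored 0.489% against 0.751% (adjusted p = 0.398) and EIF4ENIF1 1.25% against 1.34% (adjusted p = 0.960). The list test gave adjusted p = 0.755, with 2 members above and 6 below library-wide editing, the same counts adjusted over the list alone.

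Targets of let-7 and miR-17 had a median score of 2.21% under APOBEC1-DDX6, above lists of like expression at 1.19% (percentile 99.2). Of 20, 14 rose and 6 were higher and 4 lower relative to library-wide editing, the same counts adjusted over the list alone (list adjusted p = 0.0137; adjusted p = 0.167 with an estimated correlation). Of 10 selenoprotein genes 8 rose, with a median of 2.17% (percentile 96.7), and 3 were higher and 0 lower on both adjustments, over all genes and adjusted over the list alone (adjusted p = 0.0172; adjusted p = 0.175 with an estimated correlation). TXNRD1, a thioredoxin reductase, rose 46.4-fold to 2.46% ± 0.472 and SELENON 10.2-fold to 1.88%. Ribosomal protein genes rose in 48 of 53 cases and fell in 2, with 33 higher and 3 lower relative to library-wide editing and 34 and 4 adjusted over the list alone (adjusted p = 1.1e-06; adjusted p = 0.0309 with an estimated correlation). Their median score, 0.718%, was nonetheless below that of lists of like expression at 0.834%, and their control scores stood at percentile 0.03. RPL7 reached 1.14% ± 0.336, at least 94.4-fold higher, while RPL4 fell from 0.275% to 0.0164%. In the tubulin and actin list 15 of 17 rose, and 9 were higher and 0 lower, also adjusted over the list alone (adjusted p = 5.3e-10; adjusted p = 0.0309 with an estimated correlation), led by TMSB10 at 1.58% ± 0.280. Translation factors had 14 higher and 1 lower, 16 and 1 adjusted over the list alone (adjusted p = 7.1e-10; adjusted p = 0.0699 with an estimated correlation). Chromatin factors had a low median score, 0.941% against 1.42% for like lists (percentile 0.34), with 1 higher and 22 lower, 1 and 23 adjusted over the list alone, and did not pass the list test (adjusted p = 0.133). BRD2, a bromodomain protein, fell from 0.492% to 0.0989% (adjusted p = 0.00717) and the acetyltransferase gene CREBBP from 0.807% to 0.337% (adjusted p = 0.00901). CNOT7, a deadenylase of the CCR4-NOT complex, rose 13.6-fold to 2.76% and the RNA-binding protein gene PUM2 19.1-fold to 1.57%.

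Across the 10 ADAR2dd fusions with replicates, translation factors were called higher than other genes in 10 of 10, ribosomal protein genes in 9 of 10, cholesterol synthesis in 8 of 10, glycolysis in 8 of the 9 with enough members, tubulin and actin genes in 7 of the 7 with enough members and P-body factors in 7 of 10. Zinc finger genes were called lower in 6 of 10. Across the 10 replicated APOBEC1 fusions the tubulin and actin list was called higher in 7 of 9, translation factors and selenoprotein genes in 5 of 10 each (the latter called lower in 1) and P-body factors in 0 of 10 (edgeR fits with camera; lowest adjusted p = 0.423 with an estimated correlation). Ribosomal protein genes were called higher in 2 and lower in 4. The fusions shared their controls. Unchanged groups simulated against those controls gave at most 1 fusion called per list in each of 10 simulations, where the list could be simulated. Genes were drawn independently there and without a general rise in editing. The simulations therefore cannot show how often correlated genes or a general rise give a call. With an estimated correlation only the ribosomal list stayed called among ADAR2dd fusions, in 1 of them (lowest adjusted p = 0.0454 with an estimated correlation), and the ribosomal and tubulin and actin lists in 1 APOBEC1 fusion each.

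A further question was whether fusions marked the same mRNAs. Over 9550 genes, the rank correlation of scores across genes, which are not independent replicates, had a median of 0.494 between the termini of one protein with one deaminase (8 pairs). Different proteins gave 0.527 with ADAR2dd (40 pairs) and 0.587 with APOBEC1 (42 pairs). The same protein with the other deaminase gave 0.305 (16 pairs), close to 0.297 for another protein with the other deaminase (84 pairs). The 1000 highest genes shared medians of 371.5, 413.5, 350, 169 and 158.5 in the same order, where independent lists share 104.7. Scores of many fusions also ranked like their editor-only control, with a median rho of 0.493 for ADAR2dd and 0.535 for APOBEC1. The fusions with the most editing ranked least like it, LSM14A-ADAR2dd at 0.147 and APOBEC1-DDX6 at 0.306. Replicates of one fusion gave medians of 0.538 for ADAR2dd and 0.589 for APOBEC1, but between single libraries, while the values above pool the libraries of each fusion. Single libraries hold fewer reads and more counting noise, so the replicate values cannot be set against the others. LSM14A-ADAR2dd against APOBEC1-DDX6 gave 0.0990, with 144 of the 1000 highest genes shared.

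HCT116 cells carrying APOBEC1-DDX6 and LSM14A-ADAR2dd together were edited by both. A-to-I editing reached 4.52% of reads against 0.253% in cells with both unfused editors, and C-to-U editing 1.10% against 0.241% (n = 2 each). For A-to-I, RPS27 rose 97.9-fold to 27.5% ± 0.814, EBP 28.4-fold to 26.6% ± 1.34, NDUFB2 8.96-fold to 30.4% ± 0.398 and DDX6 13.4-fold to 11.6% ± 0.982. LSM4 reached 13% ± 0.813 (at least 157-fold higher) and PNRC2, which promotes decapping, 9.77% ± 0.445 (at least 83.2-fold). For C-to-U, ARL6IP1 rose 35.1-fold to 14.6% ± 0.161, B2M 18.8-fold to 12.5% ± 0.0900, SPTSSA 13.3-fold to 13.4% ± 0.836 and CCND1 to 2.02% ± 0.0322 (at least 107-fold higher). By edgeR 8869 of 9360 genes rose and 5 fell in A-to-I (1100 and 954 relative to library-wide editing), and 3562 of 7042 rose and 45 fell in C-to-U (788 and 932), where DESeq2 gave 1906 higher and limma 1938. The A-to-I falls were FANCD2 of DNA crosslink repair (1.48% ± 0.374 to no edited read), the mitotic kinase gene CIT, DYNLT1, M6PR and POR. Scores ranked across genes like those of the single fusions, with rho 0.808 against LSM14A-ADAR2dd and 0.834 against APOBEC1-DDX6. A-to-I and C-to-U scores of the same cells gave 0.280.

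Groups were compared in the dual-editor cells as well. Of 72 ribosomal protein genes 71 rose in A-to-I, with a median of 7.13% against 3.82% for like lists, and 53 were higher and 5 lower relative to library-wide editing, 58 and 5 adjusted over the list alone (adjusted p = 3.0e-26; adjusted p = 0.369 with an estimated correlation). Zinc finger genes gave 3 higher and 30 lower, 2 and 26 adjusted over the list alone (adjusted p = 0.000119; adjusted p = 0.369 with an estimated correlation), although their median score of 4.80% was above like lists at 4.10%, as was their control score. Immediate early and AU-rich mRNAs had a median of 2.28% (percentile 0.04) and a negative call (adjusted p = 0.0111; adjusted p = 0.379 with an estimated correlation), while their median fold lay above that of all genes. Of them 0 were higher and 2 lower, 0 and 0 adjusted over the list alone. In C-to-U, chromatin factors had a median of 0.674% against 1.35% for like lists, with 1 higher and 17 lower, 2 and 19 adjusted over the list alone, and did not pass the list test (adjusted p = 0.141).

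In HEK293T the same editor pair reached 5.71% A-to-I (control 0.420%) and 2.75% C-to-U (control 0.624%), with n = 2 each. RPS27A, which encodes ubiquitin fused to a ribosomal protein, rose 28.0-fold to 29.9% ± 0.0028 in A-to-I, FTL 3.49-fold to 30.2% ± 0.349 and DCP2 18.6-fold to 14.4%. EDC3 scored 9.61% ± 1.64 against 0.0408%, and DDX6, whose reads include the transgene, rose 3.15-fold to 5.58%. PMF1 scored 31.3% ± 2.49 against 26.4% ± 1.23 and did not pass (adjusted p = 0.199). In C-to-U, NDUFB5 (chromosome 3, 179604794 to 179627647) rose 3.16-fold to 24.0% ± 3.70, SRP9 of the signal recognition particle 3.42-fold to 19.8% ± 0.706 and RPS24 to 8.54% ± 0.869 (at least 258-fold higher). All 76 ribosomal protein genes rose in A-to-I, with a median of 11.2% against 5.61% for like lists, and 57 were higher and 6 lower, 64 and 7 adjusted over the list alone (adjusted p = 4.8e-42; adjusted p = 0.194 with an estimated correlation). In C-to-U 69 of 71 rose, with a median of 3.02% against 2.07%, and 46 were higher and 1 lower, 50 and 2 adjusted over the list alone (adjusted p = 8.4e-73; adjusted p = 0.0348 with an estimated correlation). CCR4-NOT and miRNA silencing factors had a median A-to-I score of 6.72% (percentile 99.3; adjusted p = 0.00629, and adjusted p = 0.213 with an estimated correlation), with 4 higher and 1 lower on both adjustments, over all genes and adjusted over the list alone. By edgeR 8841 of 9355 genes rose and 1 fell in A-to-I (816 and 559 relative to library-wide editing), and 5652 of 8358 rose and 8 fell in C-to-U (521 and 405). The A-to-I fall was DMAC2L, from 6.59% ± 0.102 to 1.54% ± 2.18. Without fusion replicate 1 the C-to-U count was 2250, and without fusion replicate 2 it was 2391, while DESeq2 gave 3009 with all libraries.

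The lines were compared by the interaction of line and editor. Reads of the tagged genes over the control differed too, at 8.02-fold for DDX6 and 4.67-fold for LSM14A in HEK293T. In HCT116 they were 1.28-fold and 1.22-fold. Differences of line and of amount of editor thus cannot be told apart. For A-to-I 236 of 8182 genes differed, 82 with a larger rise in HEK293T and 154 with a smaller one. For C-to-U 534 of 6075 differed, 127 larger and 407 smaller (edgeR). Scores of the lines ranked alike across genes, with rho 0.698 for A-to-I and 0.637 for C-to-U, and their 1000 highest genes shared 529 and 576, against 96.9 and 98.0 for independent lists. Glycolysis and translation factor lists rose less in HEK293T for A-to-I (adjusted p = 0.000281 each; adjusted p = 0.0667 with an estimated correlation), and mitotic factors rose more (adjusted p = 0.00136; adjusted p = 0.0667 with an estimated correlation). Ribosomal protein genes had a positive median difference, 0.24, while their list test was negative (adjusted p = 0.00975; adjusted p = 0.0667 with an estimated correlation). Zinc finger genes rose more (adjusted p = 0.0153; adjusted p = 0.0667 with an estimated correlation). For C-to-U, tubulin and actin genes (adjusted p = 2.8e-06; adjusted p = 0.172 with an estimated correlation), glycolysis genes (adjusted p = 0.0045; adjusted p = 0.151 with an estimated correlation) and selenoprotein genes (adjusted p = 0.00488; adjusted p = 0.151 with an estimated correlation) rose less. Oxidative phosphorylation genes and translation factors also rose less (adjusted p = 0.0447 each; adjusted p = 0.172 with an estimated correlation). Zinc finger genes (adjusted p = 0.00488; adjusted p = 0.145 with an estimated correlation) and chromatin factors (adjusted p = 0.0213; adjusted p = 0.172 with an estimated correlation) rose more in C-to-U.

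The recruitable editors ask how fast mRNAs are marked once the deaminase is brought to the granule protein by rapamycin. In HEK293T LSM14A-TRIBE-ID cells (n = 2 per time) A-to-I editing rose from 0.822% ± 0.0595 at 0 min to 1.37% at 15 min, 2.17% at 30 min, 3.59% at 60 min and 5.66% ± 0.690 at 120 min. The replicates stood apart in reads of the tagged gene LSM14A, with 1333 to 1517 RPM in replicate 1 and 734 to 846 RPM in replicate 2. DDX6 went from 5.76% ± 0.956 to 16.5% ± 1.03 at 120 min, EDC3 from 0.371% ± 0.269 to 9.90% ± 3.43, EIF4ENIF1 from 1.07% ± 1.51 to 10.7% ± 1.23, LSM14A from 0.0854% ± 0.121 to 9.22% ± 2.37 and LSM4 from 3.70% ± 0.709 to 16.3% ± 1.30, all passing at 120 min. At 15 min DCP2 (4.25% against 1.09%, adjusted p = 0.0131) and EDC3 (2.28%, adjusted p = 0.0124) had passed, while DDX6 at 8.73% (adjusted p = 0.0558) and LSM14A at 0.501% (adjusted p = 0.0891) passed only with the replicate block (adjusted p = 0.0104 and 0.00438). EIF4ENIF1 (adjusted p = 0.136) and EDC4 (adjusted p = 0.0524) also passed at 15 min only with the block (adjusted p = 0.0273 and 0.0453). XRN1 at 30 min passed without the block (adjusted p = 0.0434) but not with it (adjusted p = 0.0598). EBP rose from 13.2% ± 1.79 to 42.6% ± 3.89 at 120 min, MORN2 from 12.9% ± 1.53 to 45.2% ± 5.42 and TCOF1, a ribosome biogenesis factor, from no edited read to 11.6% ± 0.966 (at least 406-fold higher), whereas PMF1 scored 50.1% against 54.1% (adjusted p = 0.609). P-body factors had a median of 0.185% at 0 min, 0.779% at 15 min and 5.06% at 120 min. Over the same times ribosomal protein genes went from 0.352% to 0.465% and 3.88%, zinc finger genes from 0.541% to 1.12% and 2.86%, and oxidative phosphorylation genes from 0.0384% to 0.0366% and 1.80%. Chromatin factors stood above P-body factors at first, with 0.502%, 1.41% and 4.91%, as did CCR4-NOT and miRNA silencing factors with 0.437%, 1.26% and 3.79% (3.04% against 3.12% at 60 min). Of 25 P-body factors 19 had enough edited reads to be tested at 120 min and all 19 rose, and 6 were higher and 2 lower relative to library-wide editing, the same adjusted over the list alone (adjusted p = 0.0124; adjusted p = 0.898 with an estimated correlation). Of the 6 not tested, PNRC1 scored 0.123% against 0.260% at 0 min, the ribonuclease gene ZC3H12A 0% against 1.30%, LSM6 0% at both times, and LSM1, LSM3 and LSM7 0.656%, 0.596% and 0.295% against 0%. By edgeR 1044 of 6212 genes rose and 5 fell at 15 min (151 and 43 relative to library-wide editing), 4159 and 2 of 7311 at 30 min (819 and 266), 6463 and 0 of 8107 at 60 min (1290 and 474), and 7173 and 4 of 8284 at 120 min (1518 and 717). Falls were RP2, NDFIP2, GSTCD, PABPC1 and MSI2 at 15 min, AP4S1 and TMED3 at 30 min, and RAD51B, COMMD10, ABHD18 and CAB39 at 120 min. AP4S1 and COMMD10 did not pass with the replicate block (adjusted p = 0.0690 and 0.0631). RAD51B, a recombination factor, fell from 6.79% ± 1.28 to no edited read (at least 3.46-fold lower). Without fusion replicate 1 the counts were 2, 1395 and 4014 at 15, 30 and 60 min. Without fusion replicate 2 they were 0 at 15 min, with 1708 genes higher at unadjusted p under 0.05, and 2032 at 30 min. With all libraries DESeq2 gave 233, 2041 and 4286 at 15, 30 and 60 min, and limma 0 at 15 min (1622 at unadjusted p under 0.05) and 2677 at 30 min. The median score over 10642 genes had made 12.6% and 14% of its rise by 15 min in replicates 1 and 2, and 63.0% and 67.2% by 60 min.

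**Figure D2:**
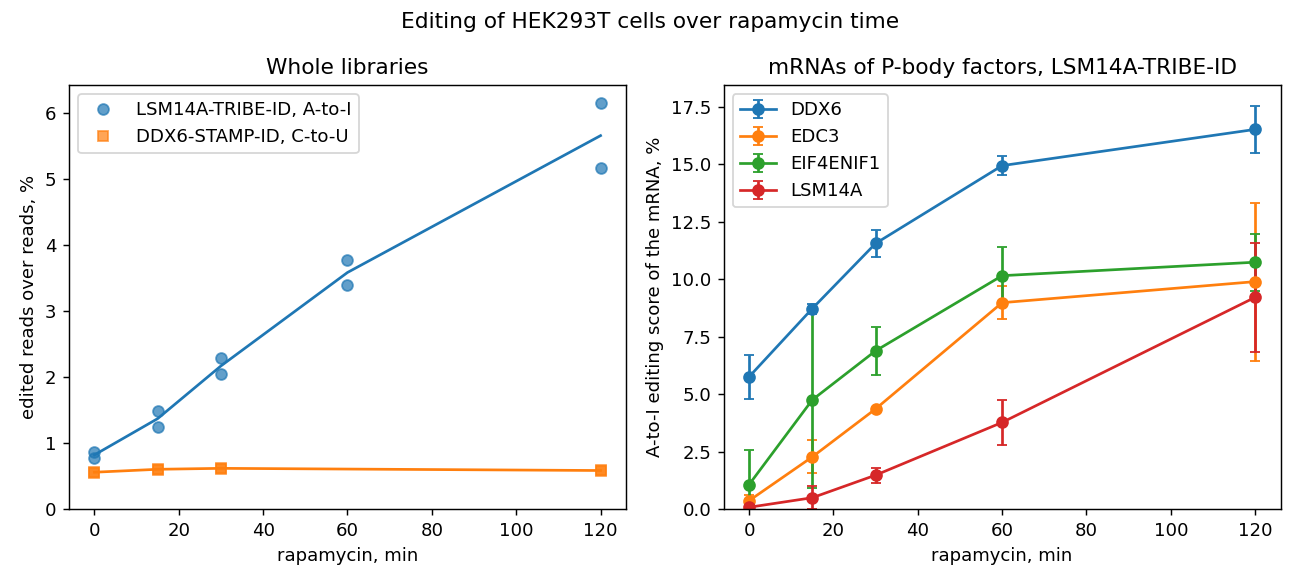
Left, edited reads as percent of all reads per library against minutes of rapamycin, with lines through the means, for LSM14A-TRIBE-ID (A-to-I) and DDX6-STAMP-ID (C-to-U). Right, scores (percent, mean ± SD, n = 2) of DDX6, EDC3, EIF4ENIF1 and LSM14A in LSM14A-TRIBE-ID cells, with DDX6 going from 5.76% to 16.5%.

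DDX6-STAMP-ID cells gave 0.560% C-to-U editing at 0 min, 0.605% at 15 min, 0.619% at 30 min and 0.586% at 120 min (n = 2 each). Each later library, at 0.575% to 0.625%, stood above both 0 min libraries (0.552% and 0.568%). None stood above both libraries of the HEK293T control with unfused editors, at 0.616% and 0.632%, which is another line with its share taken over other genes. CKB, which encodes brain creatine kinase (chromosome 14, 103519667 to 103522830), rose from no edited read to 0.452% ± 0.212 at 15 min (at least 28.1-fold higher) and stood at 0.258% ± 0.0919 at 30 min (at least 16.1-fold), and RPLP1 fell from 0.797% to 0.00878% at 15 min. CD99 had the highest score at 120 min, 14.7% ± 1.07 against 12.3% ± 1.51 at 0 min (adjusted p = 0.966). DDX6 scored 0.158% against 0.101% and DCP2 1.13% against 1.04% at 120 min, with adjusted p = 0.989 and 0.996. By edgeR 1 gene rose and 1 fell of 6298 at 15 min, and 2 rose and 0 fell of 6237 at 30 min, CKB and RPL27 (0.563% ± 0.0775, at least 13.8-fold higher). Here limma gave 0 at 15 and 30 min (143 and 179 at unadjusted p under 0.05) and DESeq2 0 at 30 min (43). At 120 min 0 rose and 0 fell of 6192, with 219 higher and 110 lower at unadjusted p under 0.05, and DESeq2 and limma also gave 0. A replicate block gave a few more genes at 30 and 120 min, as stated with the alternatives below. Without either 15 min library the count at 15 min was 0 (146 and 148 genes higher at unadjusted p under 0.05), without either 0 min library it was 2, and without any 1 library the count at 30 min was 0 (164 to 228 at unadjusted p under 0.05). In simulated data of this size, 10% of genes with a 3-fold change were recovered.

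Uninduced APOBEC1-DDX6 cells were compared with uninduced APOBEC1 control cells to describe the background of the lines. WNT16, a secreted Wnt ligand (chromosome 7, 121325367 to 121341104), fell from 168.9 TPM ± 5.13 to 1.70 ± 0.336 (n = 3 and 3), a log2 change of -5.98 ± 0.09 (SE). The phosphodiesterase gene PDE4B had a log2 change of -4.85, the serotonin receptor gene HTR7 -4.12, and PRKACB, a catalytic subunit of protein kinase A, -3.57 (108.9 to 8.26 TPM). ALPP, which encodes placental alkaline phosphatase (chromosome 2, 232378751 to 232382889), rose from 1.33 TPM ± 0.496 to 41.2 ± 1.79 (log2 4.20), HOXB8 from 10.6 to 71.7 TPM (2.65) and the glucose transporter gene SLC2A3 by 2.47. DDX6 itself stood at 69.3 TPM ± 0.390 against 80.3 ± 1.25, a log2 change of -0.21 (adjusted p = 0.000396). By limma 3783 of 16250 genes rose and 3193 fell, and after quantile normalization 3304 rose and 3483 fell. The groups did not overlap for 8912 genes (54.8%, where chance gives 10%). Changes are on the log2(TPM + 1) scale, which understates those of low genes.

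Several groups moved together in the uninduced APOBEC1-DDX6 cells. Mitotic factors rose in 32 of 36 cases and fell in 0, also 32 and 0 adjusted over the list alone, led by the kinase CDK1 at 0.94 and the cytokinesis protein ANLN at 0.79 (adjusted p = 4.3e-15; adjusted p = 0.0477 with an estimated correlation). Interferon-stimulated genes rose in 25 of 35 and fell in 1, 26 and 1 adjusted over the list alone, with IFI6 at 1.40, BST2 at 1.26 and IFIH1, an RNA sensor, at -0.39 (adjusted p = 3.1e-07; adjusted p = 0.0477 with an estimated correlation). Unfolded protein response and ATF4 targets rose in 26 of 36 and fell in 4, the same adjusted over the list alone, with SDF2L1 at 1.02 and the mTORC1 inhibitor DDIT4 at -1.30 (adjusted p = 2.9e-06; adjusted p = 0.0477 with an estimated correlation). Proteasome genes rose in 17 of 31 and fell in 0, 20 and 0 adjusted over the list alone (adjusted p = 2.3e-05; adjusted p = 0.0477 with an estimated correlation), and selenoprotein genes rose in 14 of 18 and fell in 2, 15 and 2 adjusted over the list alone (adjusted p = 0.000105; adjusted p = 0.0477 with an estimated correlation). Ribosomal protein genes fell in 46 of 80 and rose in 7, 47 and 8 adjusted over the list alone, by small amounts such as -0.24 for RPL9 (adjusted p = 1.3e-06; adjusted p = 0.182 with an estimated correlation). Immediate early and AU-rich mRNAs fell in 20 of 38 and rose in 4, the same adjusted over the list alone, with the transcription factor KLF4 at -2.01 and ZFP36L1 at -1.43 but the phosphatase DUSP6 at 0.53 (adjusted p = 1.8e-05; adjusted p = 0.321 with an estimated correlation). P-body factors rose in 8 of 26 and fell in 4, 9 and 4 adjusted over the list alone, with PNRC1 at -0.78 and LSM3 at 0.52, and were not called (adjusted p = 0.576).

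DDX6-knockout cells were compared with wild type by translation efficiency, the log2 of polysome over total RNA, for which 1 value per genotype and line was used. These differences have no replicate check. In HCT116 KHDRBS1, an RNA-binding splicing regulator (chromosome 1, 32013868 to 32060850), stood at -0.58 in the knockout against -2.29, 1.71 higher, LMNB1, which encodes lamin B1, was 1.69 higher, and the anti-apoptotic gene MCL1 (chromosome 1, 150574558 to 150579610) 1.64 higher. The PCNA-binding factor gene PCLAF (chromosome 15, 64364304 to 64387687) changed by -1.84 and the actin-binding peptide gene TMSB4X by -1.15. DDX6 itself stood at -0.18 against -1.71, and translation efficiency does not check the knockout. PATL1 was 1.35 higher, PNRC2 1.03, LSM14A 0.93, EIF4ENIF1 0.89 and LSM6 changed by -0.40. Over 14974 genes the median change was 0.25, with 76.4% higher in the knockout (exact 95% interval 75.7 to 77.0). Quantile normalization, which makes the mean change 0 by construction, gave a median of -0.03 with 46.6% higher. The change ran against wild-type efficiency across the 10529 genes of both lines (rho -0.676, and -0.280 after quantile normalization). The wild-type value is itself part of the change, so some of this correlation is built in. The lists are therefore described relative to random lists of like expression and to lists matched on wild-type efficiency.

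Ribosomal protein genes had a low change in HCT116, with a median of -0.22 against 0.19 for random lists and 9 of 80 higher (percentile 0, also after quantile normalization and among lists matched on wild-type efficiency), led by RPL41 at -0.84 and RPS12 at -0.80. Nuclear-encoded oxidative phosphorylation genes had a median of -0.21 against 0.28 (percentile 0, and 0.75 when matched on wild-type efficiency), with UQCRH of complex III at -0.72. Replication-dependent histone genes had -0.20 (percentile 0, and 14.4 when so matched), but 0.23 at percentile 35.4 for the 10 genes of level 5 or more. Mitochondrial ribosomal protein genes had -0.04 (percentile 0, and 46.3 when so matched). CCR4-NOT and miRNA silencing factors had 0.64 against 0.38, with 32 of 32 higher (percentile 99.2, and 92.7 when so matched; 0.20 and percentile 94.8 after quantile normalization), among them the adaptor TOB1 at 1.23 and CNOT11 at 1.29. The let-7 and miR-17 targets had 0.65 (percentile 98.6, and 95.1 when so matched, with 0.17 and 89.4 after quantile normalization), with ZFP36L1 at 1.56, and chromatin factors 0.53, with 55 of 56 higher (percentile 99.4, and 13.2 when so matched, with 0.14 and 94.3 after quantile normalization). Zinc finger genes had 0.29 (percentile 99.4, and 4.32 when so matched) and -0.02 (percentile 93.8) after quantile normalization. P-body factors had 0.41 (percentile 67.1), and -0.08 (percentile 7.24) after quantile normalization.

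In HEK293T changes were smaller, with a median of 0.08 over 11160 genes and 62.1% higher (61.2 to 63.0), or 49.9% after quantile normalization. WDR75, a ribosome biogenesis factor (chromosome 2, 189441474 to 189475552), was 1.30 higher, the condensin subunit gene NCAPG 1.12 and the chaperone gene HSP90AA1 1.04. The intermediate filament gene NES (chromosome 1, 156668763 to 156677407) changed by -1.65 and the collagen gene COL5A1 by -1.41. Mitotic factors had a median of 0.42 against 0.11 for like lists, with 33 of 37 higher (percentile 100, also when matched on wild-type efficiency and after quantile normalization). Chromatin factors had -0.03 (percentile 0.01, 2.96 when so matched and 2.97 after quantile normalization), with KMT2B at -0.70 and ARID1A at -0.65, and ribosomal protein genes 0.05 (percentile 0.17, 83.7 when so matched and 1.54 after quantile normalization). Zinc finger genes had 0.10 (percentile 99.5, and 8.93 when so matched), and -0.07 (percentile 0.94) after quantile normalization. DDX6 was 0.67 higher, PNRC2 0.84 and the nonsense-mediated decay helicase gene UPF1 changed by -0.58. Across 10529 genes, which are not independent replicates, the changes of the lines had rho 0.313 (0.165 after quantile normalization), and wild-type efficiencies -0.01.

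**Figure D3:**
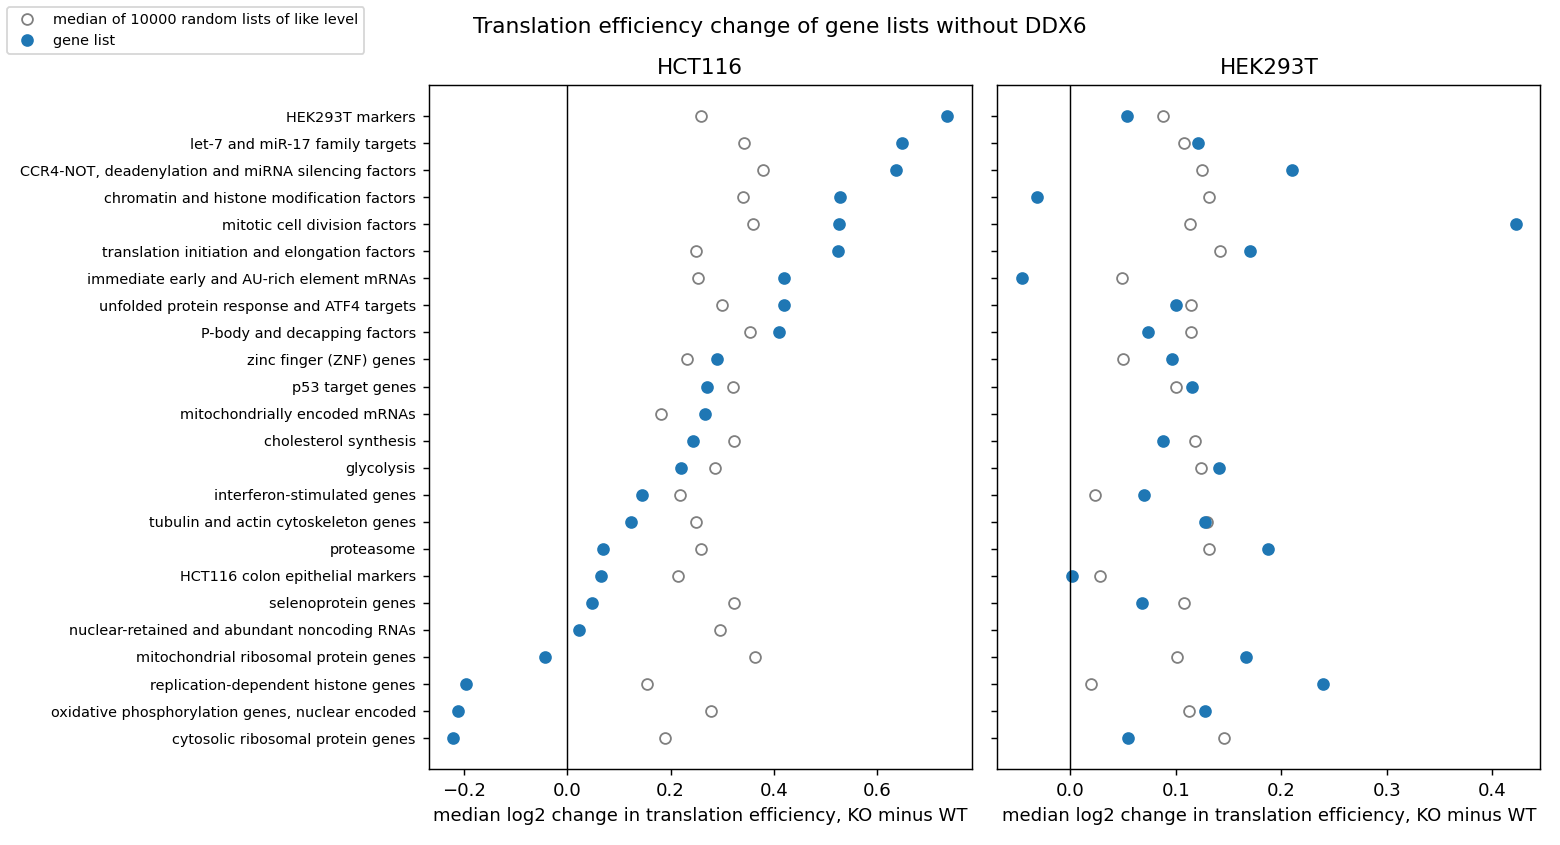
Median change in log2 translation efficiency, knockout minus wild type, for each gene list (filled points) and for random lists of like expression (open points), in HCT116 and HEK293T panels with different horizontal scales. Ribosomal protein genes lie at -0.22 and 0.05; after quantile normalization, not drawn, medians of several lists change sign, such as zinc finger genes (0.29 and 0.10 to -0.02 and -0.07) and, in HCT116, P-body factors (0.41 to -0.08) and translation factors (0.52 to -0.05).

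mRNAs marked by both editors were set against the knockout to ask whether their translation changes without DDX6. They were chosen by score in the fusion cells alone, without the control. mRNAs that unfused editors also mark can thus be among them. In HCT116 235 genes were among the 1000 highest of both A-to-I and C-to-U scores, where 87.9 would be shared by independent lists. SNRPD3, a core spliceosome protein (chromosome 22, 24555650 to 24574971), was 1.53 higher in translation efficiency in the knockout, the prion protein gene PRNP 1.49, PERP 1.35 and MEX3C 1.29, while MORN2 changed by -0.61. The median change of the 234 with a value was 0.41 against 0.31 for other genes (percentile 99.9), and after quantile normalization 0.01 against 0.01 (percentile 44.3). Among lists matched on wild-type efficiency the percentile was 20.97, and with the 300 highest genes of each score 30.4 (34 genes), while with the 2000 highest it was 100. Their wild-type translation efficiency was lower, at -0.50 against -0.07. In HEK293T 331 genes were in the set (92.9 by independence), of which 297 were higher in the knockout. The actin-bundling protein gene PLS3 (chromosome X, 115561174 to 115650861) was 1.01 higher, FAM91A1 0.91 and the glycerol phosphate dehydrogenase gene GPD2 0.87, while RBM12 changed by -0.89. Their median change was 0.31 against 0.09 (percentile 100; 85.1 after quantile normalization). Lists matched on wild-type efficiency had 0.27 (percentile 99.94), and the set's wild-type efficiency was higher, at 1.15 against 0.26. The lines shared 116 of these genes.

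Nanopore reads of the dual-editor cells, 1 library per line, gave the poly(A) tail of reads edited by both editors and of other reads of the same gene. In HCT116 CBX3, a heterochromatin protein (chromosome 7, 26201443 to 26213607), had a tail of 26.5 in 22 doubly edited reads against 160.0 in 476 others, and the Wnt inhibitor DKK1 14.6 against 134. The splicing regulator MBNL1 (chromosome 3, 152243632 to 152465780) went the other way, at 183 against 40.9. DDX6 was shorter by a difference of -32.1, LSM14A -14.1 and PNRC2 -88.4. Tails of DDX6 and LSM14A can include transgene reads, as these cells carry fusions of both proteins. Over 1094 genes the median tail was 119 in doubly edited and 150 in other reads, and 81.9% of genes were shorter (exact 95% interval 79.5 to 84.1). In HEK293T the RNA helicase gene DDX5 (chromosome 17, 64498254 to 64506866) had a difference of -101 and RBMX -95.5, while CCNI had 19.3. Over 678 genes the medians were 71.0 and 107, with 85.4% shorter (82.5 to 88.0). Cholesterol synthesis genes in HCT116 had a median difference of -67.5 against -40.4 for like lists, with 7 of 8 shorter (percentile 0.87). The let-7 and miR-17 targets there went the other way, at 8.2 against -33.2, with 2 of 5 shorter (percentile 97.3). Ribosomal protein genes in HEK293T had -22.0, with 49 of 50 shorter (percentile 99.8), while their other reads had a median tail of 82.4 against 100 for like lists (percentile 0). In HCT116 they had -39.8 against -40.6 (percentile 56.6). The median share of doubly edited reads was 2.15% over 12 ribosomal protein genes in HCT116 and 7.76% over 50 in HEK293T, against 11% and 17.8% for like lists. The unit of tail length was not given in the sources used here and nucleotides are presumed. A class had as few as 8 reads, and genes are not replicates, so no test was made.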

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

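The tests of the DDX6-STAMP-ID and tail patterns and the other splits of the samples were chosen only after the results were seen, and those of the doubly edited mRNAs after the data were examined but with their bounds written before their own results were seen.

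The rise in A-to-I editing over the control differed between HCT116 and HEK293T dual-editor cells for 236 of 8182 genes, and the rise in C-to-U editing for 534 of 6075 genes, by the interaction test in edgeR. The lines also differed in reads of the tagged genes over the control, so line and amount of editor cannot be told apart. LSM14A reads, which no comparison of the DDX6-STAMP-ID cells used, stood at 542.15 RPM or more in each of those libraries, against 203 to 206 in the HEK293T control libraries, 2.64 times the highest control. Reads of ADARB1, which encodes ADAR2, stood at 978 to 1155 RPM there, against 628 to 632 RPM in the control that carries unfused ADAR2dd. Whether these cells hold a second editor beside the one on the label was not tested.

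The mRNAs edited by both editors had a higher median change in translation efficiency without DDX6 than other mRNAs in both lines, in the values as deposited. In HCT116 this was lost after quantile normalization (percentile 44.3) and with the 300 highest genes (30.4), so it is not settled there. In HEK293T the wild-type translation efficiency went with much of it, since lists matched on that efficiency had a median change of 0.266, against 0.314 for the set and 0.0898 for the background. The set stood at percentile 99.94 among those lists, but the lists were matched in only 20 bins of wild-type efficiency. Differences of efficiency within a bin remained, so the percentile does not decide whether that efficiency accounts for all of the change. In HCT116 the percentile was 20.97, as that dependence would give. A candidate biological explanation, that more marked mRNAs change more, had a partial rank correlation across genes of 0.215 in HEK293T, above the bound set beforehand, and of 0.07265 in HCT116, between the bounds. C-to-U scores alone gave 0.317 and 0.139, and A-to-I scores alone 0.0535 and -0.0223, so that it rests on 1 of the editors and stays open in both lines. In HEK293T quantile normalization lowered the percentile of the set to 85.1, so the authors' scaling stays open as a technical explanation, and there is no replicate.

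C-to-U editing of the DDX6-STAMP-ID cells rose less over the minutes of rapamycin than A-to-I editing of the LSM14A-TRIBE-ID cells, with a highest ratio of a later over a 0 min library of 1.131 against at least 5.98 at 120 min. The lowest reads of a DDX6-STAMP-ID library were 1.06 times the highest of the LSM14A-TRIBE-ID libraries at 120 min, which argues against too few reads. Editing at 0 min was 20.35% of that of the HEK293T dual editor, which argues against a level already at its ceiling. The HEK293T control with both unfused editors had 0.616% and 0.632%, and no DDX6-STAMP-ID library (0.552% to 0.625%) stood above both. Editing above that of this control was therefore not seen at any time. The control is another, induced line, and its share was taken over 11012 genes, against 10716 for DDX6-STAMP-ID. The amount of editor was not matched either, so the values do not decide whether these cells edited above an unfused editor. The lowest DDX6 reads were 3.128 times the highest control, which argues against cells without extra DDX6. A slower or weaker editor and failed recruitment of the deaminase may each remain, as neither was tested.

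Reads edited by both editors had shorter tails than the other reads of their gene in both lines. Medians resting on few reads do not account for this, since with at least 20 reads in each class the lowest share of shorter genes was 89.47%. That long reads with short tails could be kept or called differently was not tested, and no biological explanation was tested. The share of doubly edited reads went with the tail of the other reads across genes, with rho 0.362 in HCT116 and 0.354 in HEK293T, and with the tail of the doubly edited reads, with rho 0.410 and 0.331, but hardly with the difference, with rho 0.0784 and 0.0296.

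For APOBEC1-DDX6 the real split of the 6 libraries gave 4557 genes and the highest of the others 0, and for the uninduced cells the real split gave 6976 and the highest of the others 3. In each case 1 of the 10 splits gave a count as large, and 10 splits are too few for a share under 0.05.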

How the results depend on the processing

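Choices named in the design were made before the data were examined. The fit relative to library-wide editing, DESeq2, the plain limma fit, the filter at 100 reads, APOBEC1-DDX6 libraries 2 and 3 counted as 1, for the gene lists of translation efficiency the matching on wild-type efficiency, and for the doubly edited set the matching on wild-type efficiency, the quantile scaling and the level filter were chosen after seeing the data. The bounds for that matching of the doubly edited set were written before its result was seen. Over the main results and their alternatives, 155 values kept direction and side of the threshold or stayed within the spread, 52 moved, 5 lost the threshold and 1 reversed. Of 1633 values of 144 named genes, 1452 kept their side of the threshold, 181 lost it and 0 changed direction. Where a result did not hold, the cause was not tested unless named.

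Relative to library-wide editing, which removes the general rise by construction, genes higher numbered 1059 for LSM14A-ADAR2dd, 918 for APOBEC1-DDX6, 1100 and 788 for the HCT116 dual editor (A-to-I and C-to-U), 816 and 521 for HEK293T, and 151, 819, 1290 and 1518 for LSM14A-TRIBE-ID at 15, 30, 60 and 120 min. DESeq2 gave 1906 for HCT116 dual C-to-U, 3009 for HEK293T dual C-to-U, 233, 2041 and 4286 for LSM14A-TRIBE-ID at 15, 30 and 60 min, and 0 for DDX6-STAMP-ID at 30 min, with 43 genes higher at unadjusted p under 0.05. limma on log2 scores gave 1938 for HCT116 dual C-to-U, 0 and 2677 for LSM14A-TRIBE-ID at 15 and 30 min, and 0 for DDX6-STAMP-ID at 15 and 30 min. With 10 times the pseudocount limma gave 0 for LSM14A-TRIBE-ID at 15 min and 0 for DDX6-STAMP-ID at 15 and 30 min. At unadjusted p under 0.05 the plain limma fit gave 1622, 143 and 179 genes higher in these comparisons, where edgeR's adjusted counts were 1044, 1 and 2. With a replicate block DDX6-STAMP-ID gave 11 at 30 min and 4 at 120 min, in place of 2 and 0, and the block moved no other main count by over 1.5 times. Of the 88 list calls in 14 comparisons, 9 held with an estimated correlation (over all 88, adjusted p 0.0309 to 0.898 with an estimated correlation) and 78 with the replicate block, none of them reversed. With fry, which tests a list against no change and so does not bear on calls made against other genes, 74 passed in the same direction and 14 had the other direction. Same-numbered DDX6-STAMP-ID libraries had correlations of -0.032 to 0.027, and in the uninduced cells (-0.0259 to -0.0166) no library went best with its own number. The block there gave 3322 higher and 2698 lower.

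Leaving out each replicate gave 6241 to 7532 genes higher for LSM14A-ADAR2dd, 3853 to 4023 for APOBEC1-DDX6, 8129 to 8610 and 2791 to 3043 for the HCT116 dual editor, 6508 to 8565 and 2250 to 5290 for HEK293T, 0 to 1177, 1395 to 3801, 4014 to 6247 and 5561 to 6976 for LSM14A-TRIBE-ID at 15, 30, 60 and 120 min, 0 to 2, 0 to 0 and 0 to 0 for DDX6-STAMP-ID at 15, 30 and 120 min, and 3142 to 3633 higher and 2543 to 3006 lower for the uninduced cells. The 15 min LSM14A-TRIBE-ID count fell to 2 without fusion replicate 1 and to 0 without fusion replicate 2, where a lone library is assumed to vary like the others. The DDX6-STAMP-ID median score at 120 min, 0.614%, was 0.627% over genes of level 5 or more and 0.612% over all genes.

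The share of genes with higher translation efficiency in the knockout was 70.9% without a filter, 80.5% at level 5 or more and 46.6% after quantile normalization in HCT116, and 54.1% without a filter and 49.9% after quantile normalization in HEK293T, where quantile normalization sets the mean change to 0 by construction and so says nothing of the balance. Changes of the lines had the same sign in 56.92% of genes without a filter, 64.14% at level 5 or more and 56.27% after quantile normalization, against 62.95%. For the doubly edited set HCT116 fell to percentile 44.3 after quantile normalization, 30.4 with the 300 highest genes and 21.0 when matched on wild-type efficiency, while it was 100 with the 2000 highest genes and 99.9 with the single-editor fusions. HEK293T fell to 85.1 after quantile normalization. Tails were shorter in 89.5% of HCT116 and 95.4% of HEK293T genes with at least 20 reads per class. No paired analysis was possible because translation efficiency had 1 value per genotype and line. Tests, pseudocounts, DESeq2, leaving out replicates and a fit of all polysome libraries were not run for it for the same reason, nor were camera, an estimated correlation or a block for the doubly edited set, and total RNA level had no file used here.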

Other observations

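Lists that the report did not describe for the uninduced lines also moved. Tubulin and actin genes rose in 17 of 24 and fell in 3, 19 and 3 adjusted over the list alone, with TUBA4A at a log2 change of 0.70 (limma, adjusted p = 6.1e-05; adjusted p = 0.238 with an estimated correlation). Mitochondrial ribosomal protein genes rose in 33 of 76 and fell in 6, 34 and 6 adjusted over the list alone (adjusted p = 0.00527; adjusted p = 0.0532 with an estimated correlation). CCR4-NOT and miRNA silencing factors fell in 13 of 32 and rose in 3, the same adjusted over the list alone, with the deadenylase subunit PAN2 at -0.65 and BTG3 at 0.47 (adjusted p = 0.00404; adjusted p = 0.274 with an estimated correlation). Zinc finger genes fell in 79 of 368 and rose in 35, 69 and 34 adjusted over the list alone, with ZNF276 at -1.03 and ZNF367 at 1.11 (adjusted p = 0.0216; adjusted p = 0.0477 with an estimated correlation).

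Other lists were not called but held members that changed. Chromatin factors rose in 9 of 56 and fell in 15 on both adjustments, over all genes and adjusted over the list alone (adjusted p = 0.427), with the deacetylase HDAC4 at -1.46, EZH2, a histone methyltransferase, at 0.47 and the DNA methyltransferase DNMT1 at 0.51. Targets of let-7 and miR-17 rose in 7 of 24 and fell in 10, also adjusted over the list alone (adjusted p = 0.241), with HMGA2 at -1.03 and the cell cycle transcription factor E2F1 at 1.04. Glycolysis genes rose in 5 of 20 and fell in 8, 5 and 9 adjusted over the list alone (adjusted p = 0.183), with LDHA, lactate dehydrogenase A, at -0.69. Cholesterol synthesis genes rose in 10 of 25 and fell in 9, 11 and 9 adjusted over the list alone (adjusted p = 0.770), with SQLE, squalene epoxidase, at 0.47. Among HCT116 epithelial markers 6 of 15 rose and 5 fell, 6 and 6 adjusted over the list alone (adjusted p = 0.943), with the keratin KRT18 at 0.80 and KRT19 at -0.70. Of 7 HEK293T markers 1 fell, ZIC2 at -0.36, also 1 adjusted over the list alone (adjusted p = 0.943). Oxidative phosphorylation genes rose in 30 of 79 and fell in 9 (adjusted p = 0.120), p53 targets rose in 9 of 27 and fell in 7 (adjusted p = 0.623), and translation factors rose in 11 of 36 and fell in 11 (adjusted p = 0.753). Adjusted over the list alone these were 30 and 9, 9 and 9, and 11 and 12. Mitochondrially encoded mRNAs rose in 4 of 13 and fell in 8, also adjusted over the list alone (adjusted p = 0.107), histone genes rose in 2 of 24 and fell in 5, also adjusted over the list alone (adjusted p = 0.50), and nuclear RNAs rose in 2 of 17 and fell in 5, 2 and 6 adjusted over the list alone (adjusted p = 0.245).

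The uninduced lines differed in other ways. The 10 most abundant genes took 33.4% to 33.7% of TPM in the APOBEC1 control libraries and 30.8% to 31.1% in the APOBEC1-DDX6 libraries. DDX6 stood at 70.9 and 71.1 TPM in the uninduced dual-editor control and at 96.4 and 92.2 TPM in the uninduced ADAR2dd control.

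In HEK293T C-to-U editing, proteasome mRNAs had a low median score of 0.741% against 2.43% for like lists (percentile 0.01) and oxidative phosphorylation mRNAs 1.52% (percentile 0.08), with 16 of 20 and 37 of 49 members higher than in the control. Among doubly edited mRNAs, ribosomal protein genes made up 6 in HEK293T (2.31 by independence) and 0 in HCT116 (1.47). Selenoprotein genes made up 3 (0.554) and 2 (0.289), let-7 and miR-17 targets 3 (0.892) and 0 (0.496), and p53 targets 2 (0.861) and 3 (0.537), in HEK293T and HCT116 in that order. Wild-type translation efficiency had rho -0.676 with its own change across genes in HCT116 and 0.373 in HEK293T, but -0.280 and -0.161 after quantile normalization, so the opposite signs depend on the scaling. The wild-type value is subtracted in its own change, which pushes these correlations toward negative values. The negative ones are thus partly built in, while the 0.373 of HEK293T has the other sign. With the wild-type efficiency of the other line, rho was -0.016 for the HCT116 change and -0.371 for the HEK293T change.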
